A study of Homo sapiens with 12 samples.

How the data were processed

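The values were MAS5 signal intensities on a linear scale, as deposited, and the submitters' processing notes name MAS5 without a version, which is not given in the sources used here. The trimmed mean of every array was 500.1 after leaving out 2% at each end, so the authors had scaled all arrays to the same target. The table held 54675 probe sets on 12 arrays, and raw scan files were not analysed here. The authors' labels name 2 lines, A549 in RPMI1640 and SW780 in Leibovitz L-15 medium, with siEGFP, siFFluc or siKDM3A duplexes. They do not say whether the replicates were separate cultures.

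The 62 Affymetrix control probe sets were removed. Of the remaining 54613 probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none in the annotation given, which dates from 2016. Symbols were brought up to date through gene numbers with a RefSeq gene table of assembly GRCh38.p14, which was used for names alone and matched 41037 probe sets. Probe sets were kept where the mean signal over 12 arrays was at least the 40th percentile (a signal of 29.6), which left 32768. For each gene the probe set of highest mean signal was tested, giving 14057 genes, of which 7082 had more than 1 kept probe set. Signals were taken as log2(signal + 16).

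A linear model with 6 group means was fitted in limma 3.58.1 under R 4.3.3 with a trended prior variance. The change in a line was siKDM3A minus the average of the siEGFP and siFFluc group means. The lines were averaged for the joint test and subtracted, SW780 minus A549, for the test of a different response, and siEGFP was compared with siFFluc in each line. All adjusted p-values of genes are limma's moderated tests with the Benjamini-Hochberg adjustment over the genes tested in a comparison, and 0.05 was the threshold. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

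The 29 gene lists were written from general knowledge and tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals. Lists, filter, pseudocount, model, comparisons and the alternatives were fixed before the data were examined, apart from 4 alternatives that were added afterwards: lists without SW780 siFFluc replicate 1, lists without A549 siKDM3A replicate 2, lists under median scaling, and the comparison of control arrays between lines. Named genes were KDM3A and CCND1, the 10 largest rises and 10 largest falls past the threshold in each line and in both together with both siKDM3A arrays beyond all 4 control arrays of the line, the 5 largest differences between lines in each direction, and up to 4 list members of smallest p per list and comparison. One further item of this rule is not reported here.

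The procedure was tested on simulated arrays in which 200 of 14057 genes were changed in 1 line. At a true change of 1.5-fold it recovered 48.5% of them in A549 and 52% in SW780, and at 2-fold 80.5% and 73.5%. False calls made up 7.62% and 5.45% of the calls at 1.5-fold and 9.55% and 8.70% at 2-fold, above the nominal 5%. There were 0 calls in the line left without change, the raised list was called, and 0 of 28 other lists were. Those lists were random genes with independent simulated noise, so they do not show how often lists of correlated genes are called falsely. In these runs about as many changes of 1.5-fold were missed as found, and more of the calls were false than the threshold states. Each setting was run once. The runs changed fewer genes than were called in the data (1645 in A549 and 1675 in SW780). They also gave the control siRNAs the same means and each gene 1 spread in both lines. Rates in the data may therefore differ.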

Results

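Gene expression was measured on 12 Affymetrix U133 Plus 2.0 arrays in 2 human cancer cell lines, the lung adenocarcinoma line A549 and the bladder carcinoma line SW780. Cells of each line were transfected with siKDM3A, a small interfering RNA against the histone demethylase KDM3A, which removes methyl groups from H3K9, or with 1 of 2 control siRNAs, siEGFP and siFFluc. This gave 6 groups of 2 arrays, all from RNA taken 24 h after transfection at 100 nM. Median signal ranged from 50.3 to 59.1 between arrays, and the share of probe sets with a signal above 100 ranged from 38.9% to 41.6%. The median set the siKDM3A arrays apart in A549 and, less clearly and in the opposite direction, in SW780. Both siKDM3A arrays lay below all controls in A549 (53.1 and 51.9 against 57.4 to 59.1). In SW780 they lay above them, 1 of them barely (58.1 and 54.3 against 50.3 to 54.2). The ratio of the GAPDH 3' to 5' control probe sets lay between 0.894 and 0.999 on all 12 arrays. The same ratio for beta-actin set the siKDM3A arrays apart in opposite directions, at 1.51 and 1.61 in SW780 against 1.39 to 1.44 in its controls and at 1.16 and 1.19 in A549 against 1.20 to 1.29. Replicate arrays correlated across genes at a Pearson r of 0.982 to 0.989, where genes are not independent replicates. The most uneven pair was siFFluc in SW780, with an SD of the log2 difference of 0.479 against 0.357 to 0.434 in the other 5 pairs. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical. Gene signals are given as mean ± SD over 2 siKDM3A arrays and 4 control arrays of a line, and changes as log2 fold change ± SE on the log2(signal + 16) scale.

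The targeted transcript was examined first. KDM3A fell by 0.97 ± 0.10 in A549, from 1391 ± 106 in the control arrays to 702 ± 14.1 (adjusted p = 8.02e-05), which left 50.5% of the control signal. In SW780 it fell by 0.86 ± 0.10, from 394 ± 33.6 to 210 ± 18.5 (adjusted p = 2.63e-04), which left 53.3%. In both lines the 2 siKDM3A arrays lay below all 4 control arrays, and the sizes of the falls did not differ between lines by the test of the difference (0.11 ± 0.15, adjusted p = 0.743). The other KDM3A probe set gave signals of 1.2 to 19.9, below the filter on dim probe sets, and was not tested. CCND1, which encodes cyclin D1 and drives entry into the cell cycle, fell in both lines together (-0.43 ± 0.07, adjusted p = 7.63e-04). CCND1 alone in A549 went from 5001 ± 580 to 3837 ± 146 (-0.37 ± 0.10, adjusted p = 0.0231). This call ended under median scaling (adjusted p = 0.143), when siFFluc was the only control (adjusted p = 0.195) and when A549 siKDM3A replicate 1 was left out (adjusted p = 0.194), within a range of 0.00439 to 0.195 over the alternatives. CCND1 in SW780 went from 5268 ± 628 to 3743 ± 74.3 (-0.48 ± 0.10, adjusted p = 0.00588), and the call ended without SW780 siKDM3A replicate 1 (adjusted p = 0.0635), the highest over the alternatives.

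**Figure D1:**
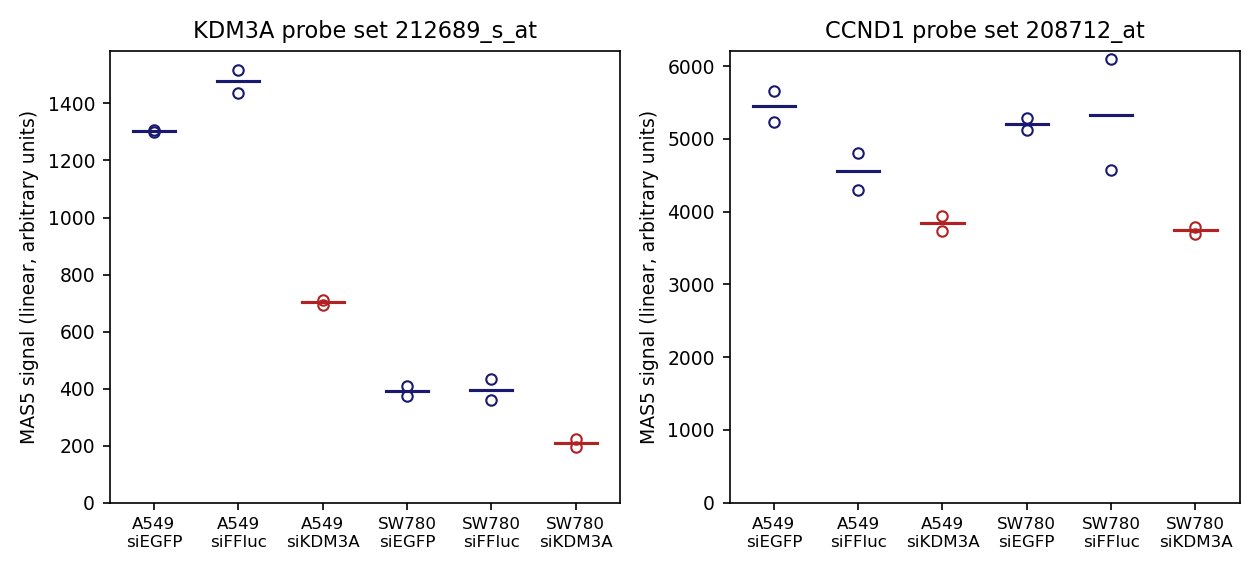
MAS5 signal (linear, arbitrary units) of the KDM3A and CCND1 probe sets on each of the 12 arrays, with circles for arrays, lines for group means, red for siKDM3A and dark blue for the control siRNAs. KDM3A lay at 693 and 712 on the siKDM3A arrays of A549 and at 197 and 223 on those of SW780, below every control array of the same line.

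The next comparison asked which other transcripts moved in A549 when KDM3A was lowered. In A549, 11 of 23 inflammatory genes fell and 12 of 38 mitosis genes rose, with none of either list moving the other way. The control siRNAs differed from each other for both lists in A549 too (camera adjusted p = 4.78e-07 for inflammatory genes and 0.00125 for mitosis genes). The prostaglandin synthase gene PTGS2 fell from 4643 ± 1355 to 2228 ± 182 (-1.01 ± 0.12, adjusted p = 1.43e-04). The neutrophil-attracting chemokine gene CXCL3 fell from 3308 ± 601 to 1517 ± 54.9 (-1.10 ± 0.13, adjusted p = 2.12e-04). CDK1, the kinase that starts mitosis, rose from 10950 ± 773 to 15360 ± 210 (0.49 ± 0.07, adjusted p = 7.19e-04). The steepest falls were of single genes outside these groups, among them SFRP1, a secreted antagonist of Wnt signalling, which fell to 322 ± 8.27 from 1898 ± 140 (-2.50 ± 0.16, adjusted p = 9.29e-07).

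Of the 14057 genes tested, 1645 changed in A549, 749 higher and 896 lower. Large changes were mostly falls, with 342 of the 418 changes of at least 1.5-fold, a split that depends on scaling, with 116 rises and 275 falls after quantile normalization and 210 and 236 under median scaling. The 10 largest falls under the fixed rule were of SFRP1, CNRIP1, KIF3B, KRT80, EIF5A2, IL1RAP, ZNF836, LOC646214, ST3GAL3 and BEST1, from -2.50 to -1.74. The kinesin motor gene KIF3B fell from 1827 ± 314 to 339 ± 13.8 (-2.36 ± 0.08). The keratin gene KRT80 fell from 2218 ± 183 to 467 ± 0.990 (-2.21 ± 0.09), and the translation factor gene EIF5A2 from 1419 ± 86.1 to 325 ± 16.1 (-2.07 ± 0.25). Of these 10 falls 9 kept the call with any 1 array left out and 9 against each control siRNA alone. The exception in both was ST3GAL3. The 10 largest rises, VGF, HERC2P3, GRASLND, BMP7, PPARA, NSMCE3, FOXF2, ZNF528, DHRS13 and AATBC, ranged from 1.52 down to 0.97, and 3 of them, NSMCE3, FOXF2 and DHRS13, kept the call with any 1 array left out, and 2 of the 10 against each control siRNA alone. NSMCE3, a subunit of the SMC5/6 complex, rose from 441 ± 142 to 942 ± 41.2 (1.12 ± 0.13, adjusted p = 1.82e-04). DHRS13, a dehydrogenase gene, rose from 351 ± 27.5 to 769 ± 161 (1.09 ± 0.14, adjusted p = 3.78e-04). FOXF2, a forkhead transcription factor gene, was called against both controls together (1.10 ± 0.15) but not against siEGFP alone (0.47, adjusted p = 0.118). PPARA had probe sets that moved in opposite directions in A549 by unadjusted p-values, so its rise depends on the probe set.

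Among the gene lists fixed in advance, 11 of 23 NF-kB and inflammatory genes fell in A549 and none rose (16 lower when adjusted over the list alone, list median -0.53, camera adjusted p = 1.88e-08, adjusted p = 0.0155 with an estimated correlation). Besides PTGS2 and CXCL3, they included the chemokine gene CXCL8, at 4348 ± 53.4 against 10406 ± 4116 (-1.17 ± 0.10, and -0.67 against siEGFP alone). The cytokine gene IL1B was at 327 ± 19.9 against 594 ± 135 (-0.80 ± 0.09, and -0.52 after quantile normalization). The probe set of each gene was chosen again after that normalization, so the second value may be of another probe set. Mitosis genes rose, 12 of 38 with none lower (17 higher over the list alone, median 0.16, adjusted p = 1.55e-08, adjusted p = 0.0492 with an estimated correlation). ANLN, a scaffold of the cleavage furrow, was at 9812 ± 133 against 6981 ± 544 (0.49 ± 0.06). DNA replication genes rose as a list, with 9 of 45 higher and 1 lower (12 and 1 over the list alone, median 0.12, adjusted p = 1.9e-04, adjusted p = 0.09 with an estimated correlation). Genes of the mitochondrial respiratory chain rose likewise, with 5 of 39 higher and 1 lower (6 and 1 over the list alone, median 0.13, adjusted p = 2.16e-05, adjusted p = 0.479 with an estimated correlation, and 0.133 after quantile normalization). NDUFV2 of complex I was one of these, at 6556 ± 72.3 against 5153 ± 311 (0.35 ± 0.06). Both calls ended with an estimated correlation. ER chaperones fell as a list, 5 of 19 lower (5 over the list alone, median -0.16, adjusted p = 0.00737, adjusted p = 0.102 with an estimated correlation). Genes of fatty acid synthesis did too, 3 of 15 lower (3 over the list alone, median -0.21, adjusted p = 0.0243, adjusted p = 0.15 with an estimated correlation). Neither held under median scaling either (adjusted p = 0.183 and 0.109). The ER call also ended against siEGFP alone (adjusted p = 0.676), and the fatty acid call against siFFluc alone (adjusted p = 0.0877) and without A549 siKDM3A replicate 2 (0.0758), A549 siEGFP replicate 2 (0.0528) or A549 siFFluc replicate 1 (0.0588).

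The p53 targets and CDK inhibitors moved both ways in A549, with 8 of 25 higher and 5 lower (8 and 8 over the list alone, adjusted p = 0.776 for the list). The largest of the falls was of TIGAR, a regulator of glycolysis, at 1455 ± 47.5 against 3492 ± 200 (-1.25 ± 0.06, adjusted p = 1.37e-07). RRM2B, a ribonucleotide reductase subunit, was at 515 ± 57.6 against 1005 ± 52.3 (-0.95 ± 0.08, adjusted p = 1.87e-05). The CDK inhibitor gene CDKN1A fell from 3709 ± 152 to 2583 ± 25.8 (-0.52 ± 0.07). Of the other lists, ERK targets had 9 of 26 lower and 2 higher (adjusted p = 0.138), including the receptor gene EPHA2 (-0.67 ± 0.10). NRF2 targets had 5 of 26 lower and 2 higher (adjusted p = 0.361), including the sulfiredoxin gene SRXN1 (-0.62 ± 0.06). YAP/TEAD targets had 5 of 23 higher and 2 lower (adjusted p = 0.361), with a list median of -0.04 against a mean of 0.125 and an upward test. Interferon-stimulated genes had 4 of 34 higher and 2 lower (adjusted p = 0.361), with IFIT1 at 11092 ± 202 against 7760 ± 879 (0.52 ± 0.07). HOX genes outside the HOXA cluster (0 of 22 higher, 1 lower), the integrated stress response (0 of 27 higher, 1 lower) and mesenchymal genes (1 of 25 higher, 4 lower) each had an adjusted p of 0.361. Epithelial genes (3 of 24 higher, 3 lower), fatty acid oxidation and PPAR targets (2 of 20 higher, 4 lower) and urothelial markers (0 of 16 higher, 1 lower) had adjusted p = 0.776. So did H3K9 methylation genes (1 of 12 higher) and the only gene of the HOXA cluster kept for testing. G1/S cyclins (2 of 20 higher, 2 lower), histone lysine demethylases other than KDM3A (1 of 23 higher, 2 lower) and fibroblast markers (0 of 7) had adjusted p = 0.462. The rest were heat shock chaperones (2 of 14 higher, adjusted p = 0.348), lung markers (1 of 10 lower, 0.499), and cholesterol synthesis (3 of 19 higher, 2 lower, 0.888). Then came leukocyte markers (0 of 7, 0.888), spermatid genes (0 of 4, 0.931), hypoxia targets (2 of 31 higher, 3 lower, 0.934) and ribosomal proteins (0 of 30, 0.934). The median, mean and test differed in sign for fatty acid oxidation, cholesterol synthesis, leukocyte markers and hypoxia targets in A549. Counts in these lists changed when single arrays were left out. Leaving out 1 of the 2 siKDM3A arrays raises the standard error by itself. Lower counts therefore do not show that the array left out carried the result. Without A549 siKDM3A replicate 1 the lower members numbered 3 for ERK targets, 1 for NRF2 targets, 1 for mesenchymal genes and 0 for hypoxia targets, and the higher ones 1 each for p53 targets, interferon-stimulated genes, cholesterol synthesis and epithelial genes. Without A549 siKDM3A replicate 2 they numbered 4, 2, 1 and 0, and 0, 2, 0 and 1. Of the p53 targets 3 were higher without A549 siFFluc replicate 1 and 5 without A549 siFFluc replicate 2 or A549 siEGFP replicate 1. Of the NRF2 targets 3 were lower without A549 siEGFP replicate 2 or A549 siFFluc replicate 2, the latter also leaving 2 mesenchymal genes lower and 2 interferon-stimulated genes higher. Without SW780 siFFluc replicate 1 or 2, 5 YAP/TEAD targets were lower and 5 heat shock chaperones higher, and without replicate 2, 7 interferon-stimulated genes were higher. Counts of 4 or fewer moved in other lists as well.

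Over all 14057 genes tested, the 2 siKDM3A arrays of A549 lay above all 4 control arrays for 17.0% and below them for 19.9%, where chance places 6.67% in each direction. That chance level takes all arrays of the line as interchangeable. The 2 arrays of any siRNA may share variation, so the excess alone does not show an effect of siKDM3A. The A549 count was 618 in the same direction when each control siRNA had to give the call alone. It fell to 523 without A549 siKDM3A replicate 2, to 594 without A549 siKDM3A replicate 1, and to 1075 and 1069 without A549 siFFluc replicate 1 or 2. Median scaling raised the median of all genes in A549 to 0.10 from -0.02 and turned the split of 749 higher and 896 lower into 1890 and 479. In the lists that passed, the members that moved with the list numbered 4 for mitosis, 5 for NF-kB, 4 for DNA replication, 1 for ER chaperones, 1 for the respiratory chain and 1 for fatty acid synthesis without A549 siKDM3A replicate 1. Without A549 siKDM3A replicate 2 they numbered 4, 5, 0, 2, 1 and 0. Without A549 siFFluc replicate 1, 7 mitosis and 4 DNA replication genes passed, without A549 siEGFP replicate 2, 5 DNA replication and 7 NF-kB genes, and without A549 siFFluc replicate 2, 7 NF-kB genes. Without any 1 of the A549 control arrays, 3 ER chaperones and 3 respiratory chain genes passed, and without SW780 siFFluc replicate 1 or 2, 10 respiratory chain genes.

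In SW780 the same question gave a different leading group. Interferon-stimulated genes rose together, 24 of 34, with none lower, and 10 of 26 NRF2 targets fell, with none higher. The NRF2 list did not hold with an estimated correlation (adjusted p = 0.0743 with an estimated correlation), and it differed by more between the control siRNAs in SW780 (median -0.37) than under siKDM3A (median -0.18). IFIT1, an RNA-binding antiviral protein, rose from 233 ± 54.0 to 1055 ± 31.7 (2.13 ± 0.07, adjusted p = 4.38e-09), and IFI27 from 76.3 ± 28.0 to 409 ± 21.9 (2.26 ± 0.08, adjusted p = 5.02e-09). IRF9, the DNA-binding part of the factor that turns on these genes, rose from 341 ± 43.8 to 1140 ± 109 (1.70 ± 0.08, adjusted p = 5.84e-08). Of the DNA replication genes 14 of 45 rose here, and of the mitosis genes 15 of 38 with 1 lower, the latter list not past the threshold with an estimated correlation (adjusted p = 0.0743 with an estimated correlation). KRT80 again fell, from 2488 ± 195 to 797 ± 75.3 (-1.62 ± 0.09, adjusted p = 5.75e-07).

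Of the genes tested, 1675 changed in SW780, 806 higher and 869 lower, and 430 of them by at least 1.5-fold, with 169 rises and 261 falls, a split that depends on scaling, with 89 and 365 under median scaling. The 10 largest rises under the fixed rule were of CXCL10, IFI27, IFIT1, MXD3, IFI44L, RSAD2, MX1, LOC728392, IRF9 and TCL1A, from 2.45 down to 1.57. Of these, 7 (CXCL10, IFI27, IFIT1, IFI44L, RSAD2, MX1 and IRF9) are induced by interferon. MX1, a GTPase that blocks viral replication, rose from 156 ± 62.5 to 563 ± 7.07 (1.83 ± 0.12), and RSAD2, which encodes viperin, from 41.9 ± 19.8 to 190 ± 4.03 (1.89 ± 0.26). MXD3, of the MAX dimerization family, rose from 30.6 ± 9.32 to 171 ± 39.7 (2.01 ± 0.25). Of these 10 rises 8 kept the call with any 1 array left out, all but CXCL10 (adjusted p = 0.0708 without SW780 siKDM3A replicate 1) and TCL1A. The 10 largest falls were of TRPM4, DYNC2I1, PLB1, CASKIN2, MYL10, IL1R1, LPAR2, ARSA, KRT80 and SEPTIN3, from -2.15 to -1.59. Of these, KRT80 had a mean siKDM3A signal above 100, and in the other 9 the 16 added to each signal weighs on the fold. Of the 10 falls 6 kept the call with any 1 array left out.

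The rise of the interferon-stimulated genes in SW780 (25 higher and 1 lower over the list alone, list median 0.61) had a camera adjusted p of 2.06e-17 and held with an estimated correlation (adjusted p = 0.00265 with an estimated correlation). DNA replication genes rose, 14 of 45 (22 over the list alone, median 0.18, adjusted p = 4.9e-08, adjusted p = 0.0281 with an estimated correlation), though the control siRNAs differed by as much for this list in SW780 (median 0.20). The origin recognition gene ORC6 was at 1819 ± 82.4 against 1190 ± 138 (0.61 ± 0.09), and RFC4 of the clamp loader at 5400 ± 32.7 against 4093 ± 329 (0.40 ± 0.06). Of the mitosis genes 15 of 38 rose and 1 fell (18 and 2 over the list alone, median 0.16, adjusted p = 2.12e-06, adjusted p = 0.0743 with an estimated correlation). Among them, the spindle gene HMMR was at 9149 ± 656 against 6092 ± 404 (0.59 ± 0.06), and the kinase gene AURKB at 1079 ± 11.2 against 777 ± 67.5 (0.47 ± 0.06).

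**Figure D2:**
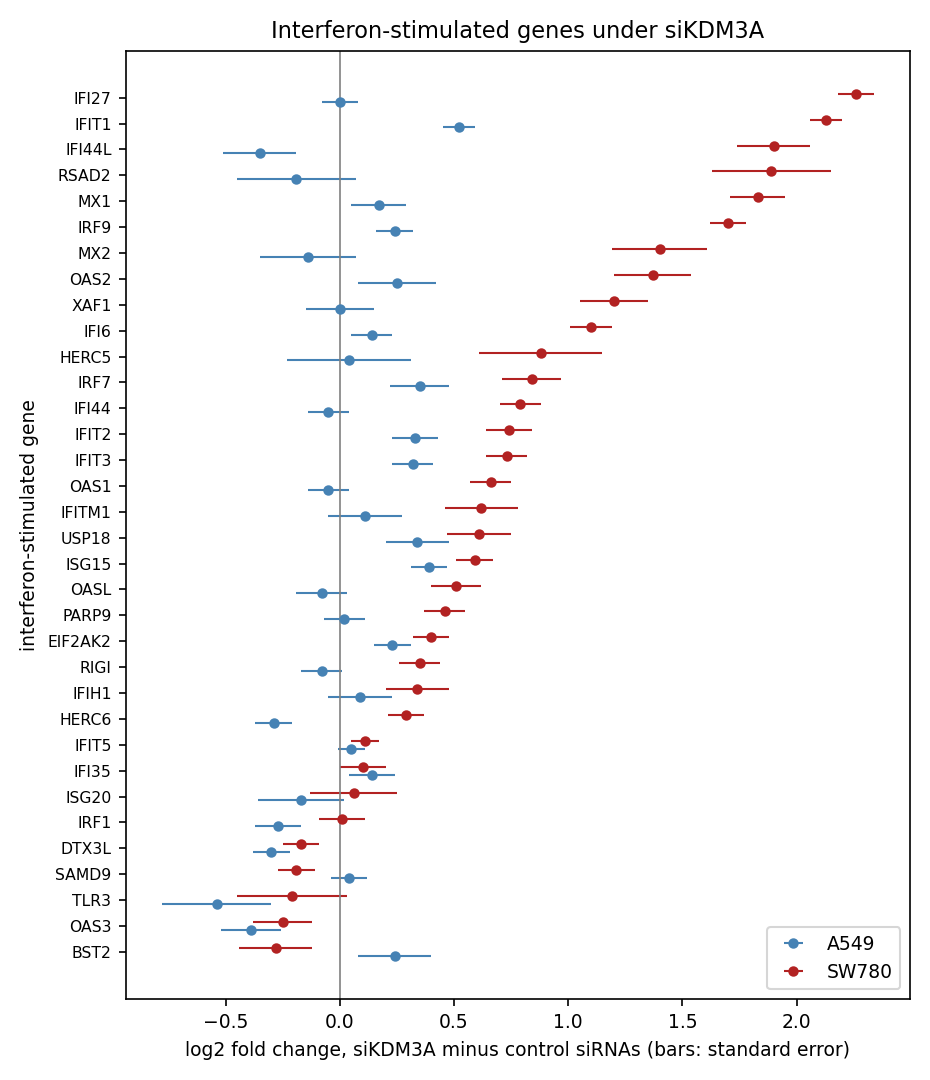
Log2 fold change (x axis, siKDM3A minus control siRNAs, bars for 1 standard error) of each of 34 interferon-stimulated genes (y axis) in A549 (blue) and SW780 (red), from 2 siKDM3A and 4 control arrays per line. The list median was 0.61 in SW780 and 0.04 in A549.

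The NRF2 targets, which handle oxidants and foreign compounds, fell in SW780 (14 lower over the list alone, median -0.18, adjusted p = 3.03e-11, adjusted p = 0.0743 with an estimated correlation). SRXN1 fell from 3682 ± 646 to 1894 ± 141 (-0.94 ± 0.06, adjusted p = 2.38e-06). The epoxide hydrolase gene EPHX1 fell from 2043 ± 494 to 887 ± 106 (-1.17 ± 0.13), and the export pump gene ABCC3 from 550 ± 113 to 251 ± 16.1 (-1.07 ± 0.11). Mesenchymal genes fell, 8 of 25 (10 over the list alone, median -0.20, adjusted p = 1.87e-04, adjusted p = 0.0743 with an estimated correlation). The matrix protein gene TGFBI was at 3189 ± 214 against 4844 ± 498 (-0.60 ± 0.06). Fatty acid synthesis genes fell, 5 of 15 (1 higher and 6 lower over the list alone, median -0.17, adjusted p = 0.00642, adjusted p = 0.0743 with an estimated correlation). The desaturase gene SCD was at 1232 ± 19.0 against 2409 ± 464 (-0.94 ± 0.09) and the citrate lyase gene ACLY at 4916 ± 35.7 against 6418 ± 625.5 (-0.38 ± 0.05). NF-kB and inflammatory genes fell as a list, 5 of 23 lower and 1 higher (6 and 1 over the list alone, median -0.21, adjusted p = 0.0108, adjusted p = 0.0743 with an estimated correlation, and 0.0961 against siEGFP alone). ER chaperones had 8 of 19 lower and 3 higher (9 and 4 over the list alone, median -0.14, adjusted p = 0.0158, adjusted p = 0.0838 with an estimated correlation, and 0.232 against siEGFP alone). The disulfide isomerase gene PDIA4 was at 3543 ± 46.4 against 6607 ± 1507 (-0.87 ± 0.12), while XBP1, a transcription factor of the same response, was higher (0.48 ± 0.06). Epithelial genes had 5 of 24 lower and 2 higher (7 and 2 over the list alone, median -0.16, adjusted p = 0.0395). This call ended with an estimated correlation (adjusted p = 0.499 with an estimated correlation), against siEGFP alone (0.814), and without SW780 siKDM3A replicate 2 (0.267), SW780 siFFluc replicate 1 (0.142) or SW780 siEGFP replicate 1 (0.0768).

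Several single members changed in lists that did not pass in SW780. TIGAR fell from 5963 ± 103 to 3058 ± 100 (-0.96 ± 0.06) and the CDK inhibitor gene CDKN1B rose from 2584 ± 83.5 to 3729 ± 67.1 (0.53 ± 0.06). Their p53 list had 3 of 25 higher and 2 lower (adjusted p = 0.274). CDK2 rose from 3512 ± 407 to 4855 ± 47.9 (0.47 ± 0.07) among the G1/S genes (4 of 20 higher, 3 lower, 0.403). The phosphatase gene DUSP4 fell (-0.64 ± 0.08) and EGR1 rose (0.45 ± 0.08) among the ERK targets (2 of 26 higher, 5 lower, 0.0736). The adjusted p was also 0.0736 for HOX genes outside the HOXA cluster (2 of 22 higher), 0.0587 for urothelial markers (1 of 16 lower), 0.125 for cholesterol synthesis (4 of 19 lower) and 0.315 for the integrated stress response (3 of 27 higher, 7 lower). It was 0.403 for heat shock chaperones (2 of 14 higher, 1 lower), 0.435 for lung markers (1 of 10 higher, 1 lower), and 0.524 for YAP/TEAD targets (2 of 23 higher, 4 lower). Values were 0.69 for hypoxia targets (2 of 31 higher, 4 lower), 0.742 for leukocyte markers (0 of 7) and 0.839 for fatty acid oxidation and PPAR targets (2 of 20 higher, 4 lower). Fibroblast markers (0 of 7) gave 0.869, and H3K9 methylation genes (1 of 12 higher), the respiratory chain (2 of 39 higher, 4 lower) and spermatid genes (0 of 4) gave 0.874. Histone lysine demethylases other than KDM3A (3 of 23 higher, 1 lower), the tested HOXA gene (0 of 1) and ribosomal proteins (0 of 30) gave 0.897. The median, mean and test differed in sign for YAP/TEAD targets, fatty acid oxidation, H3K9 methylation genes and ribosomal proteins in SW780. Counts in these lists too changed when single arrays were left out, with the limit stated for A549. Of the cholesterol synthesis genes 0 were lower without SW780 siKDM3A replicate 1, 2 without replicate 2 and 1 without SW780 siEGFP replicate 2. Of the integrated stress response genes 3 were lower without SW780 siKDM3A replicate 1 or 2, which left 0 higher, without SW780 siEGFP replicate 1, and without any 1 A549 siFFluc or siKDM3A array. ERK targets had 3 lower without SW780 siKDM3A replicate 1 and 5 higher without SW780 siFFluc replicate 1, and the respiratory chain had 9 higher without SW780 siFFluc replicate 2. G1/S genes had 2 higher without SW780 siKDM3A replicate 1 or SW780 siEGFP replicate 1 and 1 without SW780 siKDM3A replicate 2. YAP/TEAD targets had 1 lower without either SW780 siKDM3A array, and counts of 4 or fewer moved in other lists as well. Without SW780 siFFluc replicate 2 the ERK and urothelial lists passed (adjusted p = 0.0417 and 0.0424), and without SW780 siKDM3A replicate 2 the HOX list did (0.0451). The urothelial list also passed without A549 siFFluc replicate 1 or 2 (0.0463 and 0.0468). Ribosomal proteins passed without either SW780 siKDM3A array (0.00685 and 0.0132), with 0 of 30 past the threshold.

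Over all genes tested, the 2 siKDM3A arrays of SW780 lay above all 4 control arrays for 15.4% and below them for 13.3%, against 6.67% by chance in each direction. The limit stated for this chance level in A549 holds here too. The SW780 count was 540 in the same direction when each control siRNA had to give the call alone. It was 749 without SW780 siKDM3A replicate 1, 749 without SW780 siKDM3A replicate 2, and 2618 without SW780 siFFluc replicate 2. Median scaling turned the split of 806 higher and 869 lower into 365 and 1191. In the lists that passed, the members that moved with the list numbered 7 for DNA replication, 7 for mitosis, 5 for mesenchymal genes, 1 for NF-kB, 3 for fatty acid synthesis, 5 for ER chaperones and 3 for epithelial genes without SW780 siKDM3A replicate 1. Without SW780 siKDM3A replicate 2, 9 DNA replication genes passed, 8 of mitosis, 1 of NF-kB, 2 of fatty acid synthesis, 4 ER chaperones and 2 epithelial genes. Without SW780 siEGFP replicate 1, 5 ER chaperones and 3 epithelial genes passed, without SW780 siFFluc replicate 1, 3 NF-kB genes, and without SW780 siFFluc replicate 2, 9 NF-kB and 9 epithelial genes, while 3 interferon-stimulated and 4 mitosis genes were lower. Without any 1 A549 siFFluc or siKDM3A array, 3 epithelial genes passed.

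**Figure D3:**
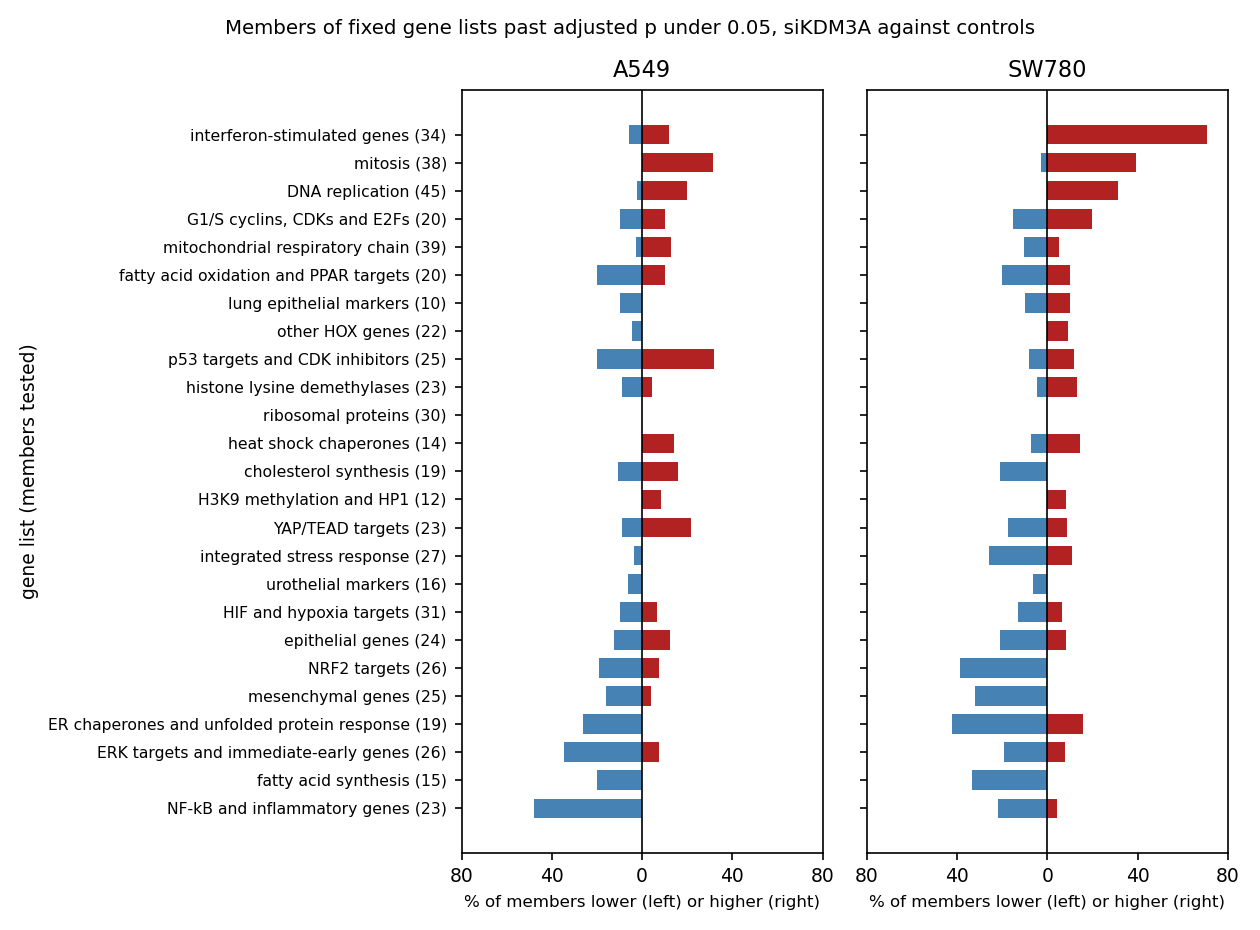
Share of the measured members (x axis, %) of each fixed gene list with at least 10 members tested (y axis, number of members in parentheses) that were higher (red, right) or lower (blue, left) under siKDM3A at an adjusted p under 0.05, in A549 and SW780. Interferon-stimulated genes had 24 of 34 higher in SW780 and 4 of 34 in A549.

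The lines were then combined in a joint test of the average change, which can pass on 1 line alone. KRT80 and KIF3B fell most among the genes shared by the lines, by 1.91 ± 0.06 and 1.80 ± 0.06 over 4 siKDM3A and 8 control arrays (adjusted p = 1.98e-09 for each). The receptors of interleukin-1 also fell, IL1R1 (-1.61 ± 0.15) and IL1RAP (-1.80 ± 0.14), as did SFRP1 (-1.62 ± 0.11) and the metalloproteinase inhibitor gene TIMP3 (-1.47 ± 0.10). Mitosis and DNA replication genes rose in the joint test, and NF-kB and inflammatory genes fell.

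The joint test called 2568 genes, 1250 higher and 1318 lower, of which 79 were higher and 242 lower by at least 1.5-fold. All 10 of the largest falls (those above with SEPTIN3, WBP2, BTRC and KATNAL1) kept the call with any 1 array left out and against each control siRNA alone. Of the 10 largest rises, 5 did with any 1 array left out, IFIT1 (1.33 ± 0.05), IRF9 (0.97 ± 0.05), PPARA (0.90 ± 0.17), FOXF2 (0.88 ± 0.10) and DHRS13 (0.83 ± 0.10). PPARA was not called against siFFluc alone (0.42, adjusted p = 0.155) or as the mean of its probe sets (adjusted p = 0.194). The others were ANKUB1, KLHL10, ZNF528, TMEM212 and ATP10A. TIGAR fell (-1.11 ± 0.04, adjusted p = 8.4e-09), as did SRXN1 (-0.78 ± 0.04) and SCD (-0.70 ± 0.06), and CDKN1B rose (0.41 ± 0.04).

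In the joint test, 20 of 34 interferon-stimulated genes were higher and 2 lower (22 and 2 over the list alone, adjusted p = 1.78e-10), and 20 of 38 mitosis genes were higher (22 over the list alone, 6.92e-10). So were 21 of 45 DNA replication genes (23 over the list alone, 4.94e-08), while 12 of 23 NF-kB genes were lower (16 over the list alone, 3.21e-07). These 4 calls held with an estimated correlation (adjusted p = 0.011, 0.0185, 0.0185 and 0.0134). NRF2 targets (10 of 26 lower, 13 over the list alone, 2.3e-06), fatty acid synthesis (6 of 15 lower, 6 over the list alone, 0.00236) and ER chaperones (9 of 19 lower and 2 higher, 11 and 3 over the list alone, 0.00247) passed at the preset correlation. They did not hold beyond it (adjusted p = 0.178, adjusted p = 0.0518 and adjusted p = 0.0518 with an estimated correlation). Mesenchymal genes (9 of 25 lower and 1 higher, 10 and 2 over the list alone, 0.00583), the respiratory chain (9 of 39 higher and 3 lower, 12 and 3 over the list alone, 0.0124) and ERK targets (9 of 26 lower and 3 higher, 9 and 4 over the list alone, 0.0124) passed likewise. Nor did these hold (adjusted p = 0.18, adjusted p = 0.631 and adjusted p = 0.204 with an estimated correlation). Of these lists, the interferon-stimulated, NRF2 and mesenchymal ones had not passed in A549 (adjusted p = 0.361 for each), the respiratory chain not in SW780 (0.874), and ERK targets in neither line (0.138 and 0.0736). Against siEGFP alone the NRF2 and ER calls ended (0.0817 and 0.266). The respiratory chain call ended after quantile normalization (0.354), against siFFluc alone (0.372) and without SW780 siKDM3A replicate 1 (0.148).

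Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at a Pearson r of 0.195 and a Spearman rho of 0.210, and no array was shared between them. Of the called genes 222 were higher in both lines and 322 lower in both, where independent lists would share 42.9 and 55.4, and 33 moved in opposite directions against 97.7. Such sharing was not particular to siKDM3A. The differences between the 2 control siRNAs correlated between lines at a Pearson r of 0.187 and a Spearman rho of 0.185, with 118 genes shared higher and 61 shared lower against 5.53 and 6.16 for independent lists. The joint count of 2568 was 1528 without A549 siKDM3A replicate 1 and 1559 without A549 siKDM3A replicate 2. Without A549 siKDM3A replicate 1, 14 DNA replication genes passed, and without A549 siKDM3A replicate 2, 5 ER chaperones and 3 respiratory chain genes. Respiratory chain genes higher numbered 4 without A549 siKDM3A replicate 1, and 5 without SW780 siKDM3A replicate 1 or SW780 siEGFP replicate 2.

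Whether the response differed between lines was tested directly, as the SW780 change minus the A549 change. Interferon-stimulated genes rose more in SW780 than in A549, 13 of 34 with a difference past the threshold and none the other way (19 over the list alone, median difference 0.46, adjusted p = 5.86e-16, adjusted p = 0.0034 with an estimated correlation). The difference was 2.25 ± 0.11 for IFI27 (adjusted p = 7.68e-07), whose A549 signal was 5394 under siKDM3A and 5378 in the controls, 1.61 ± 0.10 for IFIT1 (5.19e-06) and 1.46 ± 0.11 for IRF9 (2.62e-05). NRF2 targets fell further in SW780 (5 of 26, 11 over the list alone, median difference -0.23, 1.7e-07). That call ended with an estimated correlation (adjusted p = 0.215 with an estimated correlation) and against siEGFP alone (0.143). Inflammatory genes fell further in A549 (4 of 23, 5 over the list alone, median difference 0.24, 0.00613), a call that ended with an estimated correlation (adjusted p = 0.149 with an estimated correlation) and against siEGFP alone (0.143). IL6 differed by 1.36 ± 0.21 (0.00691, and 0.073 against siEGFP alone, where the range over the alternatives was 0.00336 to 0.0846).

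The difference passed for 392 genes, 253 with the larger value in SW780 and 139 in A549. The 5 genes with the largest positive difference were LINC00656, CNRIP1, ZNF836, IFI44L and IFI27, and those with the largest negative one were BMP7, CASKIN2, CRIP2, SESN3 and LYPD1. Of these, IFI44L (2.26 ± 0.23) and IFI27 kept the call with any 1 array left out. Other lists past the threshold were the respiratory chain (1 of 39 higher and 2 lower, 1 and 5 over the list alone, median difference -0.10, adjusted p = 2.81e-04, adjusted p = 0.392 with an estimated correlation) and HOX genes outside the HOXA cluster (0 of 22, 0 over the list alone, median difference 0.36, 0.00958, adjusted p = 0.215 with an estimated correlation). Mesenchymal genes (2 of 25 lower, 2 over the list alone, median difference -0.30, 0.0145, adjusted p = 0.272 with an estimated correlation) and p53 targets (3 of 25 higher, 9 higher and 1 lower over the list alone, median difference 0.18, 0.0405, adjusted p = 0.215 with an estimated correlation) passed too. None of these 4 held with an estimated correlation. The respiratory chain call ended too against siEGFP alone (0.182) and after quantile normalization (0.255). Mesenchymal genes lost theirs without SW780 siFFluc replicate 1 (0.1) or A549 siKDM3A replicate 1 (0.0502), and p53 targets theirs against siFFluc alone (0.216), under median scaling, where the median difference was -0.02 (0.242), and without A549 siFFluc replicate 2 (0.0851), A549 siKDM3A replicate 1 (0.0502) or 2 (0.0505), SW780 siEGFP replicate 2 (0.0666) or SW780 siKDM3A replicate 2 (0.0774). The p53 targets that differed numbered 0 or 1 without any 1 array other than A549 siEGFP replicate 2 and the SW780 siFFluc arrays, and 6 without SW780 siFFluc replicate 1.

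Median scaling moved the all-gene median of the difference between lines from 0.04 to -0.16 and turned the split of 253 and 139 into 114 and 1177. The interferon-stimulated genes stood 0.42 above the median of all genes, a distance that median scaling leaves as it is by construction. The count of 392 was below 200 without any 1 of A549 siEGFP replicate 1 (164), A549 siFFluc replicate 1 (107) or 2 (138), A549 siKDM3A replicate 1 (64) or 2 (43), SW780 siEGFP replicate 1 (145) or 2 (193), and SW780 siKDM3A replicate 1 (151) or 2 (77). It rose to 772 and 954 without SW780 siFFluc replicate 1 or 2. Without A549 siKDM3A replicate 2, 6 interferon-stimulated genes and 1 NF-kB gene passed, without A549 siKDM3A replicate 1, 7 and 2, without SW780 siKDM3A replicate 2, 7 and 1, and without SW780 siKDM3A replicate 1, 8 interferon-stimulated genes. Without A549 siFFluc replicate 1, 2 NF-kB genes passed. No NRF2 target did without A549 siKDM3A replicate 1 or SW780 siKDM3A replicate 2, and 9 did without SW780 siFFluc replicate 2. With any other array but A549 siEGFP replicate 2 and SW780 siFFluc replicate 1 left out, 1 or 2 NRF2 targets passed.

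The 2 control siRNAs were compared as a background, because neither group received siKDM3A. They were not alike in either line, with 5 of 29 lists past the threshold in A549 and 12 in SW780, and 3 in each line with an estimated correlation. Among lists not described below, histone lysine demethylases passed in A549 (camera adjusted p = 0.0452). In SW780 epithelial genes and heat shock chaperones (1.13e-05 each), the respiratory chain (4.8e-05) and ER chaperones (0.00395) passed. So did the G1/S, hypoxia and urothelial lists there (0.0146 each). None of these held with an estimated correlation. The methionine synthase reductase gene MTRR was higher under siEGFP than under siFFluc by 1.72 ± 0.09 in A549 and 1.57 ± 0.09 in SW780, and the desmosome gene DSP by 1.40 ± 0.07 and 1.48 ± 0.07. The transcription regulator gene ZFP91 went the other way (-1.29 ± 0.07 and -1.32 ± 0.07), and so did the cystine transporter gene SLC7A11 (-1.29 and -1.20).

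These genes differed in A549 among 410 in all (209 higher under siEGFP, 201 higher under siFFluc), and in SW780 among 803 (372 and 431). Genes at least 1.5-fold lower under siFFluc numbered 125 in A549 and 142 in SW780, and 59 were the same, where independent lists would share 1.26. Those at least 1.5-fold lower under siEGFP numbered 95 and 100, and 24 were the same, against 0.676. For such genes the change under siKDM3A depended on the control chosen, and DSP and CDS1 are 1 example of each kind. DSP in A549 was 0.44 against both controls, -0.26 against siEGFP alone (adjusted p = 0.0432) and 1.14 against siFFluc alone. CDS1, of phospholipid synthesis, was in SW780 1.07 against both, 2.00 against siEGFP alone and 0.14 against siFFluc alone (adjusted p = 0.544). In A549 the interferon-stimulated genes (3 of 34 lower, 7 over the list alone, median -0.21, adjusted p = 5.07e-07), inflammatory genes (6 of 23 lower, 8 over the list alone, median -0.27, 4.78e-07) and ER chaperones (3 of 19 lower, 5 over the list alone, median -0.14, 1.65e-05) were lower under siEGFP. These calls held with an estimated correlation (adjusted p = 0.0178, 0.0178 and 0.0218). Their counts in A549 ranged from 1 to 6, 2 to 6 and 1 to 4 with 1 array left out. Without A549 siFFluc replicate 1 they were 1, 2 and 2, without A549 siEGFP replicate 2 they were 1, 3 and 1, and 1 ER chaperone passed without A549 siEGFP replicate 1 or A549 siFFluc replicate 2. The interferon-stimulated genes numbered 6 without SW780 siFFluc replicate 1 or 2. In SW780 the ribosomal protein genes were lower under siEGFP, 24 of 30 (30 over the list alone, median -0.35, 1.47e-21). This did not hold with an estimated correlation (adjusted p = 0.171 with an estimated correlation) or after quantile normalization (0.361). The 24 became 1 without SW780 siFFluc replicate 1 and 0 without SW780 siEGFP replicate 2, and 11 without A549 siFFluc replicate 1 or 2 and 7 without A549 siKDM3A replicate 1 or 2. NRF2 targets (17 of 26 lower, 20 over the list alone, median -0.37, 1.85e-16) and interferon-stimulated genes (4 of 34 lower, 10 over the list alone, median -0.16, 9.27e-05) were lower under siEGFP in SW780. DNA replication genes were higher (8 of 45, with 1 lower, 15 and 1 over the list alone, median 0.20, 1.53e-08). These 3 calls held with an estimated correlation (adjusted p = 0.0483, 0.0483 and 0.0478). Without SW780 siEGFP replicate 2, 2 NRF2 targets and 1 DNA replication gene passed, and without SW780 siFFluc replicate 1, 7 and 13. DNA replication genes numbered 4 without SW780 siEGFP replicate 1 and 12 without SW780 siFFluc replicate 2. Mitosis genes were higher under siEGFP in A549 (2 of 38 higher, 1 lower, the same over the list alone, median 0.12, 0.00125) and in SW780 (7 higher, 1 lower, 10 and 1 over the list alone, median 0.09, 0.00164). Neither held with an estimated correlation (adjusted p = 0.205 and 0.139 with an estimated correlation), and the SW780 call ended without SW780 siFFluc replicate 2 (0.152). Without SW780 siEGFP replicate 2, 2 mitosis genes were higher there, and 4 without SW780 siEGFP replicate 1. In A549 1 to 3 were higher with any 1 array left out.

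The A549 count of 410 was 257 and 222 without A549 siEGFP replicate 1 or 2 and 179 without A549 siFFluc replicate 1 (213 without replicate 2). The SW780 count of 803 was 428 and 189 without SW780 siEGFP replicate 1 or 2, and 445 and 1937 without SW780 siFFluc replicate 1 or 2. It was 476 and 473 without A549 siKDM3A replicate 1 or 2, and 456 after quantile normalization, which split it into 258 and 198.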

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

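The tests of scaling, of the SW780 siFFluc array and of saturation for the interferon-stimulated genes, the test of duplex effects and the test of scaling for the ribosomal proteins were chosen after the results were seen. The response to siKDM3A differed between the lines by the test of the difference itself for 392 genes, and interferon-stimulated genes had a median difference of 0.46, SW780 minus A549. The differences of single genes were -2.408 for BMP7, -1.755 for CASKIN2, -1.507 for CRIP2, -1.287 for SESN3 and -1.227 for LYPD1. In the other direction they were 2.445 for LINC00656, 2.326 for CNRIP1, 2.293 for ZNF836, 2.256 for IFI44L and 2.252 for IFI27.

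The interferon-stimulated genes rose in SW780 with a list median of 0.61 against 0.04 in A549. For the rise in SW780, the values argue against an aberrant siFFluc array there (0.534 without it). They also argue against scaling between arrays as its source (0.584 after quantile normalization). A low level under 1 control siRNA is argued against too (0.546 as the lower of the medians against each control alone). The size of the difference between lines does depend on scaling. Median scaling moved its all-gene median from 0.038 to -0.162 and shifts the list median difference equally. Saturation of the arrays in A549 is argued against by the 10 members with an A549 control mean under 1000, whose median was -0.152 in A549 and 0.769 in SW780. Lower KDM3A and the siKDM3A duplex itself, which cells can sense as foreign RNA, cannot be told apart, because the labels name 1 siKDM3A reagent. A difference between the lines in sensing or answering the duplex may therefore underlie the pattern, and so may a role of KDM3A.

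Falls of at least 1.5-fold outnumbered rises in A549, where rises made up 18.2% of such changes (95% interval 14.8% to 22.2%), and 94 genes fell this far in both lines against 6.35 for independent lists. The pseudocount is argued against, with 17.59% rises at a pseudocount of 1. Scaling between arrays cannot be told apart from a true excess of falls: rises made up 29.67% after quantile normalization (25.4% to 34.4%) and 47.1% under median scaling. In SW780 they made up 39.3%, 36.2% after quantile normalization and 19.6% under median scaling, so median scaling moved the lines in opposite directions. Falls that follow the duplex sequence are a candidate explanation for the recurrence, since 59 genes were also lower in both lines under siFFluc than under siEGFP, where neither duplex targets KDM3A.

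Ribosomal protein genes were lower under siEGFP than under siFFluc in SW780, with a median of -0.35. After quantile normalization the median was 0.019, so scaling between arrays may explain this difference, and leaving out SW780 siFFluc replicate 1 left it at -0.287, which argues against that array as the whole cause of the median. The members past the threshold went from 24 to 1 of 30 without it, and to 0 without SW780 siEGFP replicate 2, so the count rests on single arrays. No biological explanation was tested.

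Control probe sets were tested for a single stray array 18 times, and chance gives about 1 in 20. The 18S rRNA 5' probe set was far above the others on A549 siKDM3A replicate 2 (11420 against 533 to 1678). On SW780 siFFluc replicate 1, 3 spike probe sets were far below the other SW780 arrays: ThrX-M at 539.1 (1010.7 to 1215.5), LysX-M at 358 (637.5 to 744) and PheX-M at 430.3 (821 to 935).

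Probe sets without a gene name here, which no comparison above uses, passed the threshold in both lines together 242 times among 4451, 74 higher and 168 lower under siKDM3A.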

How the results depend on the processing

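The settings for lists without SW780 siFFluc replicate 1, without A549 siKDM3A replicate 2 and under median scaling were chosen after the data were seen. Counts of changed genes moved with the settings, and where no cause is named the cause was not tested. By the model, a fold change within a line uses only the arrays of that line. Arrays of the other line act on its counts through the variance estimate alone. Replicate pairs had an SD of the log2 difference of 0.406 to 0.479 in SW780 and 0.357 to 0.371 in A549. In A549 the 1645 genes became 872 without the variance trend, 2621 with the arrays of the line alone, 757 with the controls merged into 1 group, which adds the difference between control siRNAs to the residual, 2647 probe sets when each was tested, and 418 with a fold of at least 1.5. Leaving out 1 array gave 523 to 2384, and the array left alone in its group is assumed to vary like the others. In SW780 the 1675 became 884, 883, 785, 2514 and 430 under the same settings, 894 against siEGFP alone, and 749 to 2618 with 1 array left out. In both lines together the 2568 became 1504 with merged controls, 4179 probe sets and 321 at 1.5-fold, and 1528 to 3357 with 1 array left out. The 392 genes that differed between lines became 216 without the filter, 1291 under median scaling, 88 without the trend, 154 with the mean of probe sets, 250 with replicate number as a block, 80 against siEGFP alone, 63 with merged controls and 204 at 1.5-fold, and 43 to 954 with 1 array left out. After the mean of each group was subtracted, same-numbered arrays of different siRNAs in a line correlated across genes at -0.031 to 0.012. No variation shared by replicate number was seen, which cannot show whether the cultures were paired. Between control siRNAs, the 410 of A549 became 235 without the trend (179 to 584 with 1 array left out), and the 803 of SW780 became 456 after quantile normalization, 228 without the trend, 524 with the mean of probe sets and 1274 probe sets (189 to 1937). Lists past the threshold with an estimated correlation numbered 2 in A549, 2 in SW780, 4 in both lines and 1 in the difference. The fall of KDM3A held under each alternative, from -1.056 to -0.846 in A549 and -0.941 to -0.739 in SW780. Of 196 gene results, 121 kept the call with any 1 array left out, 138 with merged controls and 152 against siEGFP alone. Of them 2 turned direction: KDM2A in SW780 went to -0.054 as the mean of its probe sets (adjusted p = 0.787), and DSP in A549 to -0.259 against siEGFP alone (adjusted p = 0.0432), as siEGFP and siFFluc differ for this gene. Probe sets with a mean signal below 29.6 were not tested, and folds of genes near that level depend most on the pseudocount.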

Other observations

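The comparison of control arrays between lines was chosen after the data were seen, as were the correlation within A549 and the groupings by control siRNA, and the test of control levels below is of a pattern noticed in these data. Uroplakin and other urothelial genes were far higher in the SW780 controls, with 15 of 16 markers higher and 1 lower (adjusted p = 4.28e-08, adjusted p = 0.0134 with an estimated correlation), for example UPK1B at 10085 against 722 in A549 and KRT13 at 13712 against 39.8. Lung epithelial markers did not set A549 apart, with 4 of 10 higher in A549 and 3 in SW780 (adjusted p = 0.761). Of the mesenchymal genes 17 of 25 were higher in A549, such as VIM at 22221 ± 842 against 29.7 ± 16.8, and 5 in SW780, such as SNAI2 at 4632 against 1823 and THBS1 at 9488 against 2526. Of the epithelial genes 19 of 24 were higher in SW780 and 3 in A549. Neither list held with an estimated correlation (adjusted p = 0.0979 with an estimated correlation for each). Of 14057 genes 9617 differed, 4204 higher in SW780 and 5413 higher in A549. The lines were also grown in different media, and no cause of these differences was tested.

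Interferon-stimulated genes were higher in the A549 controls, 29 of 34, with 4 higher in SW780 (median of SW780 minus A549 -1.50, adjusted p = 6.89e-07, adjusted p = 0.0134 with an estimated correlation). IFIT1 was at 7760 in A549 and 233 in SW780, MX1 at 2496 and 156, and IFITM1 at 2892 and 58.1. The 4 exceptions were BST2, TLR3, SAMD9 and IRF1. A candidate explanation is that members high in the A549 controls respond less there, and the tests leave it open. No array came from untransfected cells, so levels in the controls may include a response to the control siRNAs. Across the 34 members, the A549 excess in the controls correlated with the SW780 excess in the response (Spearman rho 0.657). Both quantities share the control arrays, so rho was also simulated with no such link, which gave a median of 0.011 and an upper limit of the central 95% at 0.389 over 1000 simulations. Within A549 the control level and the change correlated at a rho of 0.315 (95% bootstrap interval -0.043 to 0.642). Higher members did not respond less there by this estimate. It cannot decide the question, because levels of different probe sets need not be comparable between genes. The 10 members under 1000 there had a median change of -0.152, while IFIT1, at 7760, rose. The members are not independent replicates, and line identity goes with every other difference between the lines.

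With the controls merged, the joint test called 1504 genes, and the highest count among 99 other splits, drawn from the 225 that divide each line into 2 and 4 arrays, was 58. Of these 100 splits 1, the real one, gave as many. This cannot exclude chance, because the make-up of the other splits held their counts low. Each of the 99 left siKDM3A arrays in the large groups, which raises the residual spread, and none of them took the 4 arrays of a control siRNA as the small groups. Those groupings, tested afterwards, gave 138 genes for siEGFP and 568 for siFFluc, which points to differences between the duplexes as a structure of the samples.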
